A study of Sus scrofa with 4 samples.

How the data were processed

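RNA sequencing libraries were compared from 4 tissues of the Tibetan pig, a breed of Sus scrofa: heart, liver, lung and kidney, with 1 library per tissue. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name TopHat, a spliced read aligner, without a version. The read counter, its treatment of reads with several matches, its use of strand, the genome build and the annotation are not given in the sources used here.

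For each library the authors deposited a table with a read count and an RPKM (reads per kilobase of model length, scaled to the total reads of the library) per gene model. Per the file headers, the deposited counts are whole reads per gene, and the length of each model and the total of the library stand beside them. In each of the 4 tables the counts summed to the stated total, and the RPKM deposited by the authors equalled the count divided by length and total, with a relative tolerance of 1e-12. No table listed a model at 0 reads, so a model missing from a table was taken as 0 reads. Of 18367 model lengths, 89.5% were multiples of 3, against 33.3% by chance, so most lengths are coding lengths, and reads in untranslated regions may or may not have been counted.

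Identifiers have the form evm.model.scaffold followed by a scaffold number and a model number. The files do not pair them with gene names, and 0 of the 18367 identifiers matched either reference table of pig genes. The 36 gene lists (tissue functions, cell types, pathways) fixed before the data were examined therefore could not be matched, the planned list comparison was not run, and markers of other cell types could not be read. Chromosomes and gene annotations are not reported for the same reason. At most 2 higher and 2 lower models are named per comparison. For 1 tissue against the others, the higher models are the 2 enriched models of highest RPKM.

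Detection was set at 1 RPKM. A model was called enriched in a tissue at 10 RPKM or more there and an (RPKM + 1) at least 5 times the highest of the 3 other libraries. Pairs of tissues were compared over the 15357 models at 1 RPKM or more in any library, counting models whose (RPKM + 1) differed at least 4-fold. These folds are on the RPKM + 1 scale, which understates the change of low models. These rules, and the alternatives in pseudocount, filter, fold, scaling and missing models, were fixed before the data were examined. Rules chosen after seeing the data were the mirror rule for depleted models (10 RPKM or more in the 3 other libraries, the lowest of them at least 5 times higher, with the 2 of highest such level named), the rule for 2 tissues (both at 10 RPKM or more, the lower at least 5 times the higher of the remaining libraries, on the RPKM + 1 scale, with models ranked by the lower of the 2 values) and thinning of all libraries to 4090775 reads. Median-ratio scaling divided each library by the median of its ratios to the geometric mean, over 10247 models above 1 RPKM in all 4 libraries.

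With 1 library per tissue there is no replicate error, no p-value and no standard deviation between samples. The 95% intervals are exact: Poisson for a count, Clopper-Pearson for a share of reads or a ratio of 2 counts. For 0 reads the floor is 3 counts per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Totals were 14062622 reads in heart, 4090775 in liver, 8853076 in lung and 5486480 in kidney. At the median length of 1278 bases, 1 read was worth 0.0556 RPKM in heart, 0.191 in liver, 0.0884 in lung and 0.143 in kidney. The widest interval of any read share reported was 0.048 percentage points either side.

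The rules were tested on simulated data: Poisson libraries of the real depths over 18367 models, with 200 models changed. For each tissue against the 3 others, 0 of 68 models changed 3-fold, 68 of 68 changed 10-fold and 64 of 64 changed 30-fold were called, and 0 unchanged models were called. The 4-fold rule for pairs called 12 of 14525 unchanged models for liver and kidney, 5 for heart and kidney, 3 for liver and lung, 3 for lung and kidney, 1 for heart and liver and 0 for heart and lung. The changed models were drawn from those of middle level, none below 10 RPKM, and no simulated fold lay near the 5-fold limit. These calls therefore show only that the rule works as written. Apart from the changed models, the simulated libraries shared a single profile. The simulation holds counting error, no biological variation and none of the differences in composition on which scaling acts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.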

Results

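The libraries were made, per the series title, to provide transcript evidence for gene annotation, and the comparison their labels allow is between tissues. Heart, liver, lung and kidney of the Tibetan pig were each represented by 1 library, so every value below describes a library and has no replicate check. Reads on gene models totalled 14062622 in heart, 8853076 in lung, 5486480 in kidney and 4090775 in liver. At least 1 read fell on 18367 gene models, and 13426 of these had reads in all 4 libraries. Models are named by their identifiers, because the files do not pair them with gene names.

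Most models were detected in every tissue. At 1 RPKM or more, 10247 models were detected in all 4 libraries. Lung had the most detected models, at 14010, followed by kidney at 13208, heart at 12455 and liver at 11470. By models with any read, heart with 16522 stood above kidney with 15960, while lung with 16921 stayed first and liver with 14493 last. Models detected in lung and in no other tissue numbered 971, against 399 for kidney, 320 for heart and 171 for liver. Liver was the tissue most often missing: 1116 models were detected in the other 3 libraries and not in liver, against 426 for heart, 133 for kidney and 121 for lung. The liver library was also the shallowest. Thinned to the liver total, the counts of detected models were 12435 in heart, 13998 in lung and 13216 in kidney. By any read after thinning, heart with 15099 stood below kidney with 15638, with lung at 16222 and liver at 14493.

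The liver and heart libraries were dominated by few models. The 10 models of most reads took 27.1% of liver reads (95% interval 27.1 to 27.2), 17.0% of heart reads (17.0 to 17.0), 8.17% of kidney reads (8.15 to 8.19) and 5.65% of lung reads (5.64 to 5.67). In liver 75 models held 50% of the reads, whereas 259 were needed in heart, 690 in kidney and 831 in lung. In each library the 10 highest models by RPKM were shorter, by median length, than the 10 of most reads. These medians were 561 against 1029 bases in heart and 1071 against 1531.5 in liver. In kidney they were 468 against 1339.5, and in lung 466.5 against 3675. Of the 10 highest models by RPKM, 7 in heart, 7 in liver, 6 in kidney and 3 in lung were also among the 10 of most reads.

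**Figure D1:**
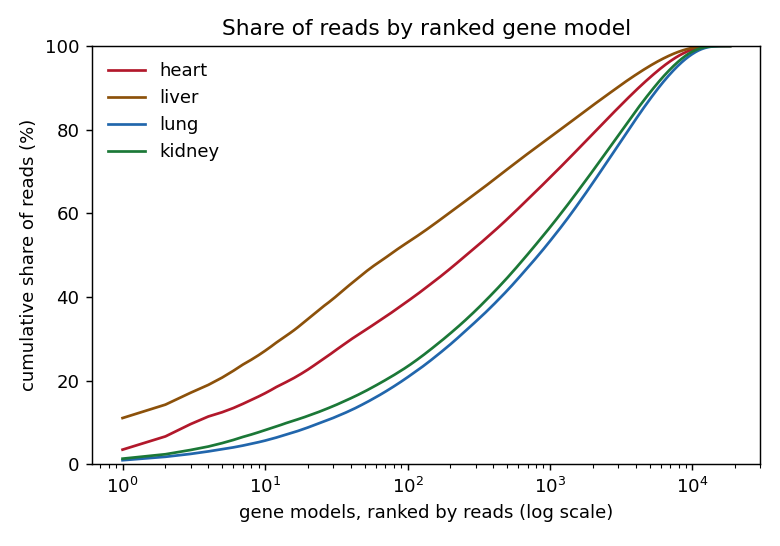
Cumulative share of reads (%, vertical axis) over gene models ranked by reads (log horizontal axis), with a line for each library. The liver line lies highest, with 53.0% of reads in 100 models, and the lung line lowest, with 20.8%.

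Heart had 382 enriched models, which took 33.7% of heart reads (95% interval 33.7 to 33.7) and 0.24% of liver, 0.484% of lung and 0.460% of kidney reads. The highest was evm.model.scaffold5062.10, at 36416 RPKM in heart and 6.91 in kidney (95% interval 4.16 to 10.8), a 5268-fold difference (3374 to 8751). It had 0 reads in liver and in lung, with upper 95% limits of 1.80 and 0.832 RPKM. Against the floor of 3 counts, heart was 24878-fold higher than liver and 53840-fold higher than lung. These are limits set by depth and not measured folds, so they do not rank liver and lung. The next, evm.model.scaffold2587.12, reached 19221 RPKM in heart and 2.28 in kidney (0.836 to 4.96), with 0 reads in liver and lung. At 1000 RPKM or more there were 35 heart-enriched models. The mirror rule gave 108 models depleted in heart, led by evm.model.scaffold35914.6 at 49.7 RPKM in heart (46.8 to 52.8) against a lowest value elsewhere of 401, and evm.model.scaffold15930.3 at 10.3 RPKM (6.80 to 15.02) against a lowest value elsewhere of 250.2. For 329 of the 382 enriched models the counting interval of the ratio lay wholly above 5, and 227 of the 382 had reads in all 4 libraries.

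Liver had 287 enriched models, which took 49.6% of its reads (95% interval 49.5 to 49.6). They included 48 models at 1000 RPKM or more and 73 that were at least 100-fold above every other library. The model evm.model.scaffold27953.4 alone reached 59403 RPKM in liver, the highest value in any library, against 63.6 in lung (59.8 to 67.6), 8.23 in kidney (6.57 to 10.2) and 1.64 in heart (1.19 to 2.21). The second, evm.model.scaffold8242.32, was at 33037 RPKM in liver and 573 in kidney (537 to 611). Depleted models numbered 206, led by evm.model.scaffold44392.1 at 36.6 RPKM in liver (32.8 to 40.7) against a lowest value elsewhere of 580, and evm.model.scaffold1235.28 at 25.9 RPKM (19.5 to 33.7) against a lowest value elsewhere of 370. The liver counts depended on scaling: under median-ratio scaling 418 models were enriched and 54 depleted in liver, and 287 and 51 of them respectively were called under both scalings. Of the 287 enriched models, 163 had reads in all 4 libraries. Liver had the fewest enriched models as deposited, and kidney did after median-ratio scaling, with 289.

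Lung had the most enriched models, 674, with a lower median level (39.6 RPKM) than those of heart (108), liver (168) or kidney (83.0). They took 13.0% of lung reads (95% interval 13.0 to 13.0). The highest were evm.model.scaffold24645.7, at 16784 RPKM in lung against 6.83 in liver (3.90 to 11.1), and evm.model.scaffold45520.21, at 7034 RPKM against 6.11 in liver (2.24 to 13.3). The second had 0 reads in heart (upper 95% limit 1.09 RPKM), and lung was 7913-fold higher than the floor of 3 counts there. Depleted models numbered 69, led by evm.model.scaffold34529.8 at 12.3 RPKM in lung (10.4 to 14.5) against a lowest value elsewhere of 601, and evm.model.scaffold47302.1 at 55.2 RPKM (50.2 to 60.5) against a lowest value elsewhere of 508. Under median-ratio scaling the count of lung-enriched models fell to 358, all of them among the 674, and depleted models rose to 154, so lung no longer had the most enriched models.

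Kidney had 368 enriched models, which took 14.2% of its reads (95% interval 14.2 to 14.2). Both of the highest were short: evm.model.scaffold42338.8, of 219 bases, reached 37344 RPKM in kidney against 342 in lung (316 to 369), and evm.model.scaffold48410.1, of 322 bases, reached 25696 RPKM against 436 in lung (412 to 461). By reads, the first ranked 5 in the kidney library. The mirror rule gave 14 depleted models, led by evm.model.scaffold34928.14 at 61.7 RPKM in kidney (57.5 to 66.1) against a lowest value elsewhere of 448, and evm.model.scaffold46697.1 at 9.17 RPKM (6.31 to 12.9) against a lowest value elsewhere of 95.5. Under median-ratio scaling kidney had 289 enriched and 29 depleted models. Of the 368 enriched models, 229 had reads in all 4 libraries.

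**Figure D2:**
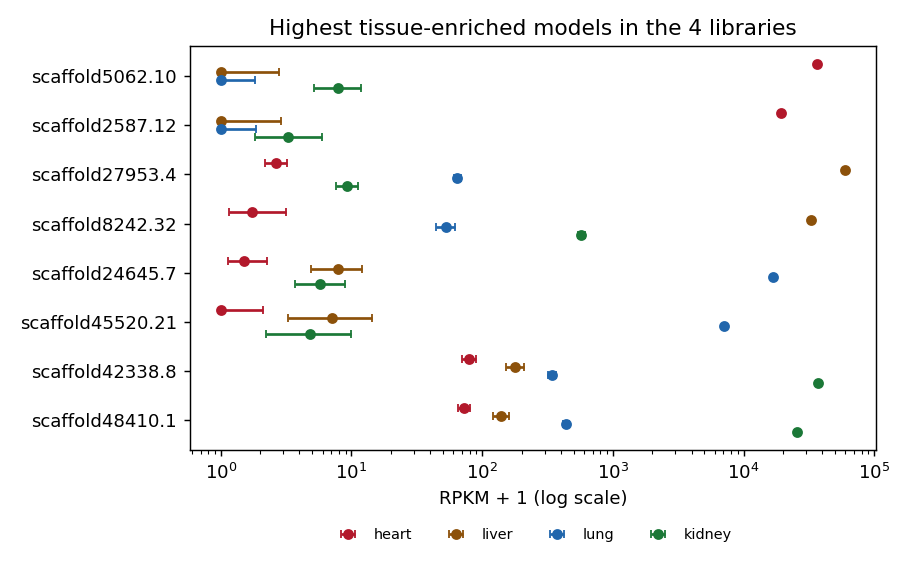
RPKM + 1 (log horizontal axis) of the 2 highest enriched models of each tissue in the 4 libraries, with exact 95% Poisson intervals of the counts as bars. The liver model of scaffold27953 reaches 59403 RPKM in liver and 63.6 in lung.

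**Figure D3:**
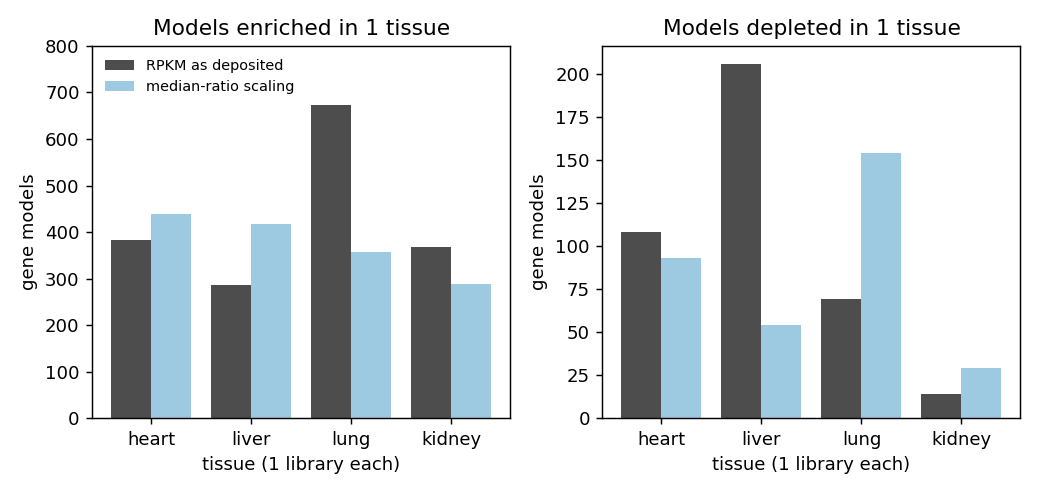
Numbers of gene models enriched (left) and depleted (right) in each tissue, with RPKM as deposited (dark bars) and after median-ratio scaling (light bars). Lung goes from 674 to 358 enriched models and liver from 206 to 54 depleted models.

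Among models that met the rule for 2 tissues, liver and kidney formed the group with the most models, 231, which took 12.7% of liver and 11.2% of kidney reads. Without the models that also met the rule for 1 of these tissues alone, 181 were left, with 6.99% of liver and 8.38% of kidney reads. Ranked by the lower of the liver and kidney values, its first members were evm.model.scaffold202417.1, at 5676 RPKM in liver and 4494 in kidney against 17.4 in lung (11.7 to 25.0), and evm.model.scaffold44125.6, at 3631 RPKM in liver and 9281 in kidney against 4.95 in lung (3.65 to 6.57). The 47 models of liver and lung took 24.8% of liver and 2.84% of lung reads, but 16 of them also met the rule for 1 tissue alone, 12 for liver and 4 for lung. The 31 others took 2.35% of liver and 1.86% of lung reads. Lung and kidney shared 119 such models, with 1.22% of lung and 1.56% of kidney reads, and heart and lung 111, with 2.83% of heart and 2.37% of lung reads. Heart and kidney shared 28, 4 of which also met the rule for heart alone, with 1.96% of heart and 0.485% of kidney reads, and the 24 others took 0.629% of heart and 0.467% of kidney reads. Heart and liver shared 10, with 0.154% of heart and 0.321% of liver reads, and the 7 that met no rule for 1 of these tissues alone took 0.143% and 0.0926%. Median-ratio scaling gave 274 models for liver and kidney, 219 of them in common, and 70 for lung and kidney.

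Between pairs of tissues, liver and kidney were the most alike and liver and lung differed in the most models. Across the 15357 models, which are not independent replicates, the Spearman correlation was 0.76 for liver and kidney and between 0.61 and 0.66 for the other 5 pairs, with Pearson correlations of 0.73 and between 0.57 and 0.64. Lung exceeded liver at least 4-fold in 4191 models and liver exceeded lung in 890. Kidney exceeded liver in 2213 models and liver exceeded kidney in 522. Heart exceeded liver in 2164 and liver exceeded heart in 1079. Lung exceeded heart in 2452 and heart exceeded lung in 942. Kidney exceeded heart in 1927 and heart exceeded kidney in 963. Lung exceeded kidney in 1948 and kidney exceeded lung in 1405.

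These splits moved with the scaling. The median model was 1.15 lower in liver than in lung on the log2 scale and 0.87 lower in liver than in kidney. The median-ratio factors were 0.614 for liver, 0.927 for heart, 1.27 for kidney and 1.38 for lung. After this scaling lung exceeded liver in 2152 models and liver exceeded lung in 1568. Kidney then exceeded liver in 1125 models and liver exceeded kidney in 859, heart exceeded liver in 1617 and liver exceeded heart in 1479, lung exceeded heart in 1548 and heart exceeded lung in 1288, and kidney exceeded heart in 1465 and heart exceeded kidney in 1216. Lung exceeded kidney in 1661 and kidney exceeded lung in 1442.

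**Figure D4:**
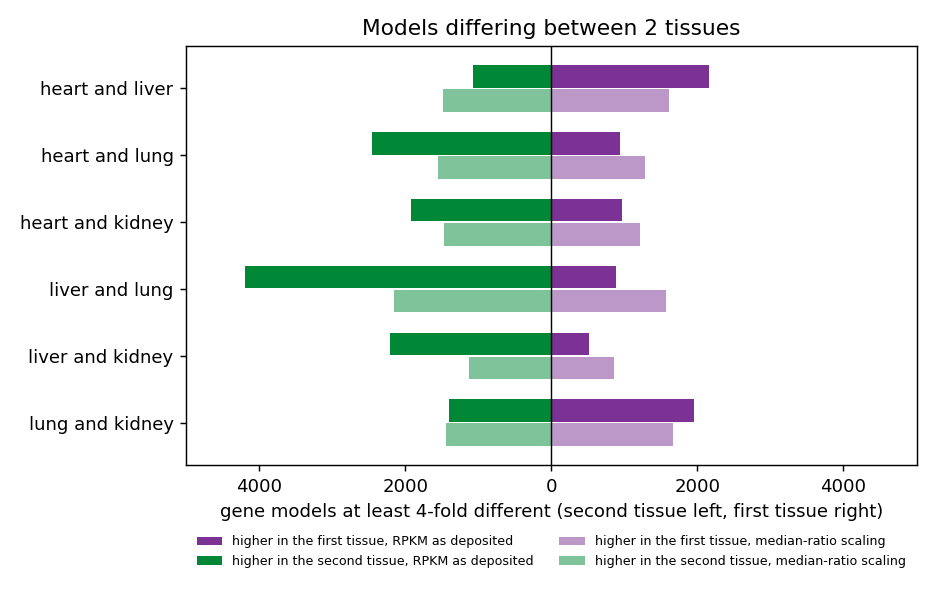
Numbers of gene models at least 4-fold different in each pair of tissues (horizontal axis), higher in the first tissue to the right and in the second to the left, as deposited (dark) and after median-ratio scaling (pale). The split of liver and lung goes from 890 and 4191 to 1568 and 2152.

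Levels also varied with the length of the model. Among 4058 models at 10 RPKM or more in all 4 libraries, the median lung minus liver difference in log2(RPKM + 1) was 0.24 for the 417 models of 153 to 432 bases and 1.24 for the 269 models of 3402 bases or more. Relative to the mean of the 4 libraries, and between the same length ranges, the lung median went from -0.19 to 0.61 and the kidney median from 0.54 to 0.17. The liver median went from -0.50 to -0.67.

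**Figure D5:**
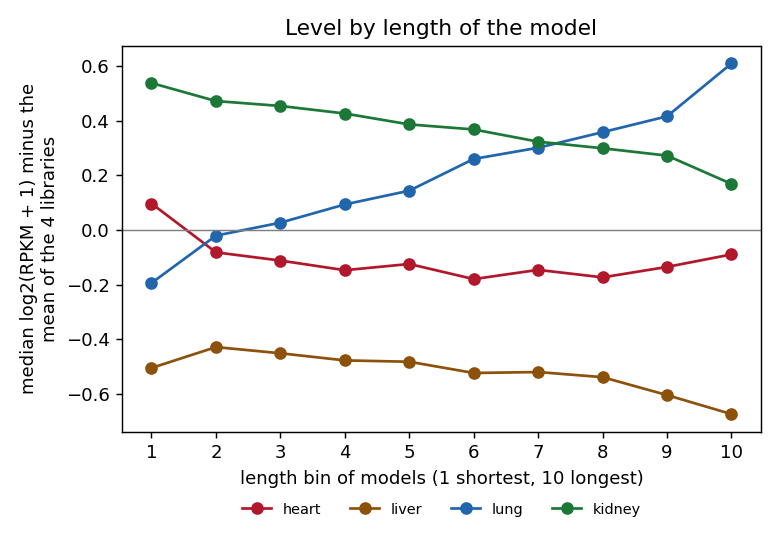
Median log2(RPKM + 1) minus the mean of the 4 libraries (vertical axis) in 10 bins of model length (horizontal axis, 1 shortest), for models at 10 RPKM or more in all 4 libraries, with edges set on all 18367 listed models so that bins hold between 269 and 519 models. The lung line rises from -0.19 to 0.61 and the kidney line goes from 0.54 to 0.17.

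Some models enriched in a tissue had reads in other libraries and some had none. With 0 reads in all 3 other libraries there were 29 heart-enriched, 16 liver-enriched, 24 lung-enriched and 17 kidney-enriched models. The 10 highest liver-enriched models stood in lung at between 0.102% and 5.13% of their liver RPKM, with a median of 0.153%. The same models had medians of 0.0025% in heart, where 2 of them had 0 reads, and 0.032% in kidney. The 10 highest heart-enriched models had medians of 0.0045% in liver, 0.023% in lung and 0.057% in kidney, with 4 of them at 0 reads in liver and 3 in lung. Medians were higher for the 10 highest lung-enriched models, at 0.619% in heart, 0.715% in liver and 1.33% in kidney. For the 10 highest kidney-enriched models they were 0.14% in heart, 1.73% in liver and 0.722% in lung, with single models at up to 18.1%.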

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

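No paired analysis was possible because each tissue had 1 library, and for the same reason no library could be left out of a group. The gene list comparison and its alternatives were not run, since identifiers carried no names. Depleted models, models of 2 tissues, correlations and thinning to equal depth were chosen after seeing the data. Counts of detected models stayed within 1.5 times under all 7 alternatives. Heart and kidney changed places when any read counted, but not when the libraries were also thinned (15099 in heart, 15638 in kidney). Neither thinning nor TPM-like scaling moved a count of any kind by more than 1.5 times. Of 140 log2 ratios of named models under alternatives, 111 stayed within their counting intervals, 29 moved and 0 reversed. Of 42 Pearson and 42 Spearman correlations under alternatives, 9 and 6 moved by 0.05 or more. A pseudocount leaves ranks as they are, so the Spearman values under other pseudocounts could not move. All 6 Spearman values that moved did so when the 1 RPKM filter was dropped. Depth limits low values most in liver, where 1 RPKM at the median length is 5.23 reads. Median-ratio scaling gave 358 enriched in lung (from 674), 54 depleted in liver (from 206), 154 depleted in lung (from 69), 29 depleted in kidney (from 14), 17 enriched in heart and liver (from 10) and 70 enriched in lung and kidney (from 119). Under it, there were 1548 higher in lung than in heart (from 2452), 1568 higher in liver than in lung (from 890), 2152 higher in lung than in liver (from 4191), 859 higher in liver than in kidney (from 522) and 1125 higher in kidney than in liver (from 2213). Restricting to models listed in all 4 files gave 227 enriched in heart (from 382), 163 enriched in liver (from 287), 229 enriched in kidney (from 368), 4 enriched in heart and liver (from 10) and 341 higher in liver than in kidney (from 522). A 3-fold minimum gave 1223 enriched in lung (from 674), 624 enriched in kidney (from 368), 243 depleted in heart (from 108), 519 depleted in liver (from 206), 154 depleted in lung (from 69) and 33 depleted in kidney (from 14). Under it, there were 268 enriched in heart and lung (from 111), 98 enriched in heart and kidney (from 28), 81 enriched in liver and lung (from 47) and 319 enriched in lung and kidney (from 119). A 10-fold minimum gave 239 enriched in heart (from 382), 271 enriched in lung (from 674), 210 enriched in kidney (from 368), 55 depleted in heart (from 108), 39 depleted in liver (from 206) and 27 depleted in lung (from 69). Under it, there were also 1 depleted in kidney (from 14), 5 enriched in heart and liver (from 10), 32 enriched in heart and lung (from 111), 12 enriched in heart and kidney (from 28), 24 enriched in liver and lung (from 47) and 150 enriched in liver and kidney (from 231), with 53 enriched in lung and kidney (from 119). A minimum of 1 RPKM in place of 10 gave 22 depleted in kidney (from 14). A pseudocount of 0.1 gave 3383 higher in heart than in liver (from 2164) and 3717 higher in kidney than in liver (from 2213). A pseudocount of 0.01 gave 3899 higher in heart than in liver (from 2164), 3888 higher in lung than in heart (from 2452), 1574 higher in heart than in kidney (from 963), 819 higher in liver than in kidney (from 522), 4073 higher in kidney than in liver (from 2213) and 3025 higher in lung than in kidney (from 1948). A 2-fold minimum gave 5061 higher in heart than in liver (from 2164), 1975 higher in liver than in heart (from 1079), 2017 higher in heart than in lung (from 942), 5998 higher in lung than in heart (from 2452), 2134 higher in heart than in kidney (from 963) and 4395 higher in kidney than in heart (from 1927). Under it, there were 1549 higher in liver than in lung (from 890), 8314 higher in lung than in liver (from 4191), 950 higher in liver than in kidney (from 522), 6825 higher in kidney than in liver (from 2213), 4403 higher in lung than in kidney (from 1948) and 3084 higher in kidney than in lung (from 1405). An 8-fold minimum gave 960 higher in heart than in liver (from 2164), 692 higher in liver than in heart (from 1079), 530 higher in heart than in lung (from 942), 997 higher in lung than in heart (from 2452), 494 higher in heart than in kidney (from 963) and 1007 higher in kidney than in heart (from 1927). Under it, there were 552 higher in liver than in lung (from 890), 1804 higher in lung than in liver (from 4191), 316 higher in liver than in kidney (from 522), 865 higher in kidney than in liver (from 2213), 802 higher in lung than in kidney (from 1948) and 697 higher in kidney than in lung (from 1405). The cause of these changes was not tested, except that a stricter fold or fewer models can only lower a count.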

Other observations

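Of the tests below, those of liver detection and of chance placement were chosen only after their results were seen. The criterion was replaced after its value was seen for 2 of the explanations, as stated where they appear.

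Some models enriched in the same tissue carried neighbouring numbers on a scaffold, in more pairs than shuffling gave. There were 31 such neighbouring pairs among liver-enriched models, 44 in lung, 26 in kidney and 18 in heart. The shuffles gave means of 3.1 in liver, 17.2 in lung, 5.1 in kidney and 5.5 in heart. Their highest values were 10 in liver, 30 in lung, 15 in kidney and 14 in heart. The most enriched models on 1 scaffold were 10 of the 126 listed on scaffold46278 for lung, 7 of 38 on scaffold8242 for liver, 5 of 8 on scaffold31207 for kidney and 4 of 32 on scaffold42051 for heart. Over the 4 tissues the pairs numbered 119 among 1711 enriched models, and the highest of 1000 shuffles of the enriched models gave 51, so chance placement among listed models is argued against. A gene split into 2 models stays open: 42.0% of the pairs had RPKM within 2-fold of each other (95% interval 33.0 to 51.4), against 28.2% of random enriched pairs. Reads shared between similar copies also stay open, since 7.56% of the pairs had lengths within 5% (3.52 to 13.9), against 5.06% of all adjacent pairs. The criterion written first, a lower bound at or below 5.06%, would have excluded shared reads; it was replaced after the value was seen because an interval that spans the comparison value excludes nothing, and no sequences were compared. No biological explanation was tested.

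Liver had the fewest models at 1 RPKM or more, 985 fewer than the next tissue. Depth made little difference to this count: over 20 thinnings to the liver total the gap averaged 996 (SD 18.8). RPKM is scaled to the library total, so this outcome was largely fixed in advance and is not counted as a test of depth. By any read, liver had 14493 models. The next lowest tissue there went from 15960 (kidney) as deposited to 15099 (heart) after thinning. The gap by any read was therefore smaller at equal depth and did not close, so depth goes with a part of it and not the whole. Reads taken by the 100 models of most reads in each library are argued against only as the whole cause. After their removal the gap averaged 517 (SD 17.5 over thinnings). This criterion was the last of 3 tried after values were seen: a single thinning set against 492.5, which is 50% of the gap, excluded the explanation narrowly, and 20 thinnings against the same bound left it undecided. The gap was smaller without these models, 517 against 996 after thinning alone, so a part of it went with them. Concentration of reads in the models left was not removed, so it stays open for the gap that remained. Median-ratio scaling left a gap of 313. A difference between the tissues themselves stays open and untested.

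The lung over liver ratio rose with model length, by 1.06 on the log2 scale between models of 153 to 432 bases and of 3402 bases or more (bootstrap SD 0.071). With 1 library per tissue, the SDs given here can describe spread across models only. They hold no variation between libraries, and models are not independent replicates. Compression of low models by the added 1 RPKM is argued against, since the rise was 0.999 (SD 0.083) at 10 RPKM or more in all 4 libraries. Length differences of enriched models could hardly be tested within this set of 4058 models. The rise was 0.994 (SD 0.082) over the 3884 of them neither enriched nor depleted. Most models of the set were kept, so the removal could move the medians little. The removal was not made over all 15357 models. Length differences of enriched models therefore stay open as an explanation. RNA or library quality cannot be told apart from tissue with 1 library each: the trend ran through broadly expressed models (Spearman 0.231 across models). Tissue biology stays open as well.

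Model numbers up to the highest listed on each of 3535 scaffolds came to 22081, of which 3714 (16.8%) were not among the listed models. The longest run of such numbers was 21.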
